A study of Homo sapiens with 12 samples.

How the data were processed

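RNA was sequenced from 12 samples of EpiVaginal, a commercial human vaginal epithelium rebuilt from primary cells on porous inserts. The samples fell into 4 groups of 3 libraries, all grown for 1 week: no hormone, 10 nM estradiol, 150 nM testosterone, and 15 nM DHT (5α-dihydrotestosterone, the ring-A-reduced form of testosterone). The labels gave all 12 libraries a single batch. Per the labels' protocols, total RNA was taken from the tissue together with its membrane, and libraries were made with a stranded kit that marks the second strand with dUTP. The protocols name poly(A) selection and ribosomal RNA removal as alternatives and do not say which was used.

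Per the submitters' processing notes, the authors used cutadapt, HISAT2 and StringTie with the human build GRCh37. Versions, settings, the annotation release and the use of strand in quantification are not given in the sources used here. Per the file headers, the deposited values are FPKM, fragments scaled to the length of the gene model and to the total of mapped fragments, in 1 table of genes and 1 table of transcripts. All 11288 gene rows and 28174 transcript rows were protein-coding, and every gene row had a mean of at least 0.5 FPKM in 1 or more of the 4 groups, as checked on the values. A gene below that level in every group was therefore not analysed here. FPKM hold no read counts, so the depth of each library is unknown, no counting interval could be given, and a value of 0 is described only as listed at 0. FPKM divides by the library total, so a change in a few abundant genes shifts all others. The 20 most abundant genes held 26.9% to 30.8% of the summed FPKM per library.

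Gene and transcript values were compared as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend. A single linear model with 4 groups was fitted to all 12 libraries, so that each gene had 1 estimate of its spread. A gene was tested if it reached 0.5 FPKM in at least 3 of the 12 libraries, which left 11239 genes and 26382 transcripts. P-values came from limma's moderated test against either direction and were adjusted by Benjamini-Hochberg over all genes or transcripts tested, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The contrasts were each hormone against no hormone, each pair of hormones, and the mean of both androgens against no hormone. The labels do not say that the libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

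The tests, the 27 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered estrogen-responsive and androgen-responsive genes, steroid receptors and steroid-metabolizing enzymes. They covered basal markers, stratified mucosal differentiation, cornification, desquamation, cell junctions, glycogen metabolism, proliferation and antimicrobial defence. They also covered inflammatory cytokines, interferon-stimulated genes, cholesterol and fatty acid synthesis, barrier lipids, matrix remodelling, water and ion transport, hypoxia and glycolysis, oxidative stress, immediate-early and heat shock genes, and mitochondrially encoded genes. Markers of other cells covered glandular or columnar epithelium, fibroblasts and smooth muscle, immune cells, endothelium and melanocytes. Lists with at least 5 tested members were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over the 23 lists tested per comparison, and again with a correlation estimated per list.

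The rule named the 12 genes per direction with the largest log2 change for each hormone against no hormone, among those past the threshold, with a group mean of at least 1 FPKM and no overlap of replicates. Where fewer than 5 genes passed, it named the 10 with the lowest unadjusted p as genes not past the threshold. Between hormones it named 5 per direction, or 5 by lowest p. It added up to 4 members per list past 0.05 adjusted over the list alone, and always a fixed set that included ESR1, ESR2, PGR, GREB1, FKBP5, KRT13 and MKI67. ESR2 and PGR were not analysed here, and some items named by the rule are not reported here. Members of a list could also be named as examples of a level. Symbols on more than 1 row, Y-linked genes and XIST were not named.

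Alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 1 FPKM, median-of-ratios and quantile scaling, robust moderation, only the libraries compared, the replicate number as a block, and leaving out each library in turn. A further 3 alternatives were chosen after seeing the data. Where a group then held 2 libraries, it was assumed to vary like the others. Count-based tests were not run, because the values are FPKM. Genes in families of near-identical members, such as keratins and late cornified envelope genes, and genes whose models overlap another are uncertain, since the assignment of shared reads is not given in the sources used here. The calculation was tested on simulated data made for estradiol against no hormone over 11239 genes. With 200 genes changed, 38.1% of those changed by 0.5 on the log2 scale, 89.7% of those changed by 1 and 99.1% of those changed by 2 were recovered, with 8.2 false calls per repeat. With 20 genes changed, the shares were 8.57%, 80.0% and 96.7%. For transcripts the shares were 0.448%, 14.3% and 68.2% with 200 changed, and 0%, 2.86% and 50% with 20 changed. The simulated values varied independently between genes, without structure shared by libraries. The shares and false calls therefore need not hold where real libraries share such structure. Figures were drawn with matplotlib 3.10.9.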

Results

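Transcript levels were measured by RNA-seq in 12 libraries of reconstructed human vaginal epithelium, 3 for each of no hormone, 10 nM estradiol, 150 nM testosterone and 15 nM DHT. The summed expression per library ran from 289420 to 334360 FPKM, and the sequencing depth behind these values is unknown. The libraries correlated with each other at r = 0.965 to 0.988 across genes, which are not independent replicates. The median correlation was 0.982 within groups and 0.981 between groups. The first principal component held 23.3% of the variance, on which estradiol replicate 1 lay lowest (-23.0) and testosterone replicate 3 highest (21.1). Mitochondrially encoded genes took 6.81% to 11.1% of the summed FPKM. No 2 libraries held identical values.

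The first comparison asked which genes changed with estradiol in the absence of other added hormones. Neurotensin (NTS), a secreted peptide, rose from 63.3 ± 22.8 FPKM (SD, n = 3) without hormone to 428 ± 11.4 FPKM (n = 3) with estradiol. This was a change of 2.79 on the log2 scale (SE 0.23, limma adjusted p = 7.85e-04). NTS (ENSG00000133636.10_2) lies on chromosome 12 at 86268073 to 86276770 of GRCh37. The aminopeptidase N gene ANPEP rose from 2.33 ± 0.793 to 9.67 ± 0.941 FPKM (log2 change 1.70, limma adjusted p = 0.00116). The glycoprotein hormone gene STC1 rose from 23.9 ± 2.28 to 78.1 ± 14.7 FPKM (log2 change 1.65), and SPINK9, a Kazal-type inhibitor of kallikrein proteases in skin, from 35.7 ± 1.93 to 97.7 ± 12.5 FPKM (log2 change 1.42). KRT9, a keratin of thick skin, rose from 17.3 ± 0.497 to 39.3 ± 1.34 FPKM (log2 change 1.14).

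GREB1, a target gene of the estrogen receptor, also rose with estradiol (log2 change 1.05, SE 0.12, limma adjusted p = 0.00334). It lies on chromosome 2 at 11622467 to 11782914. Its values were 0.964, 0.722 and 1.68 FPKM in the estradiol libraries, against 0.0044 and 0.0081 FPKM in no hormone replicates 1 and 3, and it was listed at 0 in replicate 2. At such low values the log2 change depends on the pseudocount, and was 3.48 with a pseudocount of 0.1. The call of GREB1 was lost with only the 6 libraries compared, at an adjusted p of 0.0935 in a range of 7.28e-04 to 0.0935 over 15 alternatives of limma. IL1R2, the decoy receptor of interleukin-1, rose by 0.97 on the log2 scale, and LGALS1, encoding galectin-1, by 0.87. NELL2 (0.78), SLC22A3 (0.72), FAM213A (0.71) and CSRP2 (0.69) completed the genes named among the 15 higher with estradiol.

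KRT4, a keratin of the suprabasal layers of mucosal epithelia, fell from 80.9 ± 21.7 FPKM without hormone to 8.62 ± 3.07 FPKM with estradiol (log2 change -3.10, SE 0.33, limma adjusted p = 0.00178). KRT4 (ENSG00000170477.12_2) lies on chromosome 12 at 53200333 to 53208335. CRNN, encoding cornulin of the upper layers of squamous epithelia, fell from 486 ± 164 to 140 ± 33.8 FPKM (log2 change -1.75, limma adjusted p = 0.0376). The uroplakin genes UPK1B and UPK1A, encoding tetraspanins of the urothelial surface, both fell, UPK1B from 3.59 ± 0.182 to 1.04 ± 0.314 FPKM (log2 change -1.18) and UPK1A from 80.5 ± 19.3 to 42.6 ± 2.13 FPKM (log2 change -0.88). The serpin gene SERPINB12 (-1.41), the annexin gene ANXA10 (-1.33) and the late cornified envelope gene LCE5A (-1.29) were also lower. UHMK1 (-1.34), BICC1 (-1.09), IGFL1 (-0.97), CSF2RB (-0.96) and OSBP2 (-0.74) were the others named among the 16 that fell.

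**Figure D1:**
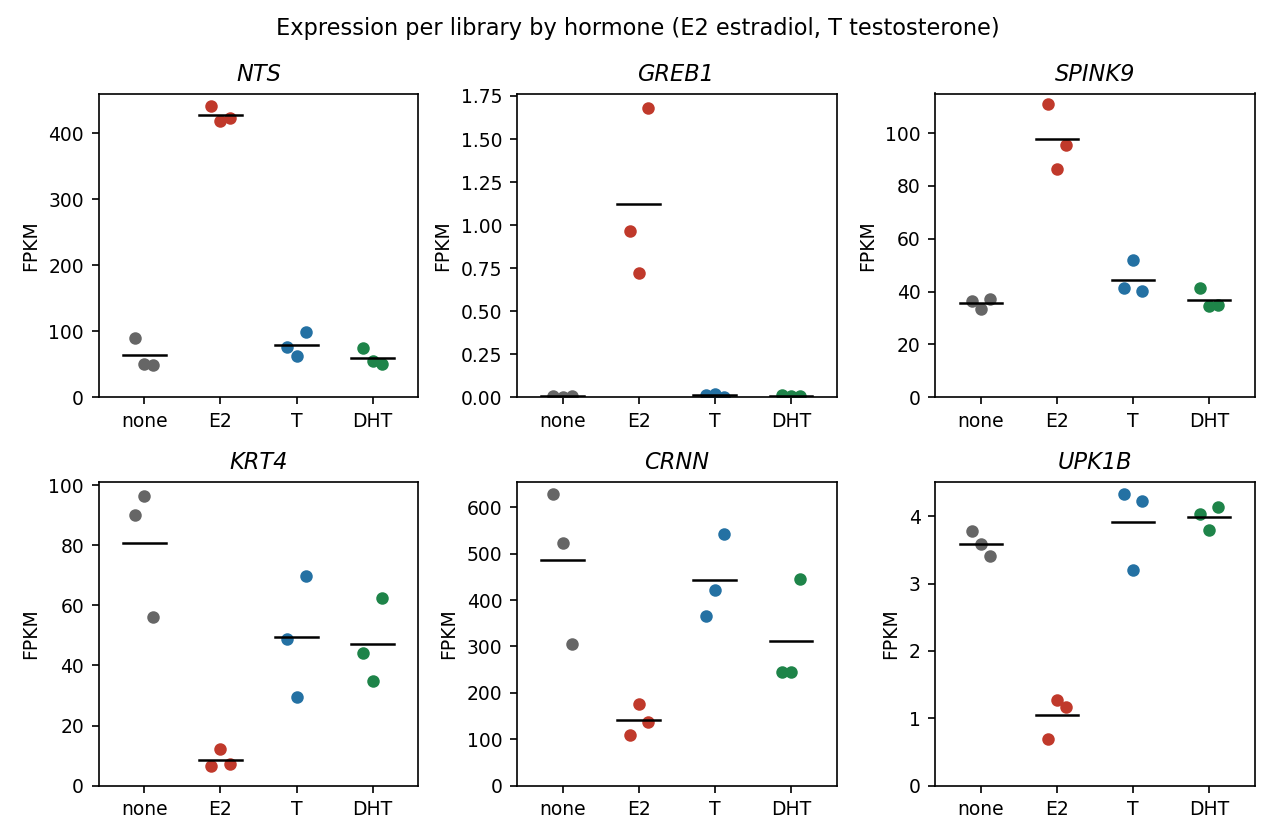
Expression in FPKM (vertical axes) of NTS, GREB1, SPINK9, KRT4, CRNN and UPK1B in the 4 groups (horizontal axes); each point is 1 of 3 libraries and each line the group mean. The estradiol libraries lie between 419 and 441 FPKM for NTS, and no library of another group exceeds 98.7 FPKM.

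Of 11239 genes tested, 31 passed the threshold of limma with estradiol, 15 higher and 16 lower, and 1125 had an unadjusted p under 0.05, against 562 by chance. In all 31 the 3 estradiol libraries lay on one side of the 3 libraries without hormone. Among all genes 1848 (16.4%) did so, against a chance share of 10%. The count was 8 without estradiol replicate 1 and 19 without no hormone replicate 2, and 18 with only the 6 libraries compared, of which 13 were among the 31. That fit ended the calls of 12 of the 24 named genes, GREB1, NELL2, SLC22A3, FAM213A, CSRP2, CRNN, SERPINB12, LCE5A, BICC1, IGFL1, UPK1A and OSBP2. A pseudocount of 0.1 ended those of NELL2, SLC22A3 and UPK1A, and median-of-ratios and quantile scaling that of UPK1A. NTS, ANPEP, SPINK9, KRT9, KRT4, ANXA10, UPK1B and CSF2RB passed without each of the 12 libraries in turn.

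The other named calls were lost without 1 or more libraries. Without estradiol replicate 1, STC1, GREB1, IL1R2, LGALS1, NELL2, SLC22A3, FAM213A, CSRP2, CRNN, SERPINB12, UHMK1, LCE5A, BICC1, IGFL1, UPK1A and OSBP2 did not pass, which left 8 of the 24 named genes. The number of named genes that passed was 14 without estradiol replicate 2 and 15 without replicate 3, and 17, 16 and 19 without no hormone replicates 1, 2 and 3. It was 20, 21 and 23 without testosterone replicates 1, 2 and 3, and 20 and 18 without DHT replicates 1 and 2. CRNN, NELL2 and UPK1A each kept their call in 3 of these 12 fits, with limma adjusted p-values of up to 0.204, 0.158 and 0.204. GREB1 fell below the filter without any one estradiol library and passed in the other 9 fits.

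Among the fixed lists, stratified mucosal differentiation was lower with estradiol. Of its 23 members tested, 21 had a negative log2 change, and KRT4 and CRNN passed over all genes. Adjusted over the list alone, 7 members fell, among them the serine protease gene TMPRSS11A, from 14.9 ± 5.39 to 6.06 ± 1.17 FPKM (log2 change -1.12), and the sciellin gene SCEL, from 135 ± 7.15 to 105 ± 5.79 FPKM (-0.35). KRT13, the keratin paired with KRT4, measured 2514 ± 458 FPKM without hormone and 1894 ± 291 FPKM with estradiol (log2 change -0.40, limma adjusted p = 0.425). Camera gave the list an adjusted p = 1.58e-10, and adjusted p = 0.178 with an estimated correlation, in a range of 9.54e-12 to 0.178 over 18 alternatives. Markers of glandular or columnar epithelium had the same sign without passing, with 7 of 8 members negative, a median of -0.40 and an adjusted p = 0.0820. Among them KRT19 measured 53.4 ± 34.4 FPKM without hormone and 34.1 ± 26.3 FPKM with estradiol, and ELF3 8.62 ± 6.12 and 3.14 ± 2.37 FPKM.

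**Figure D2:**
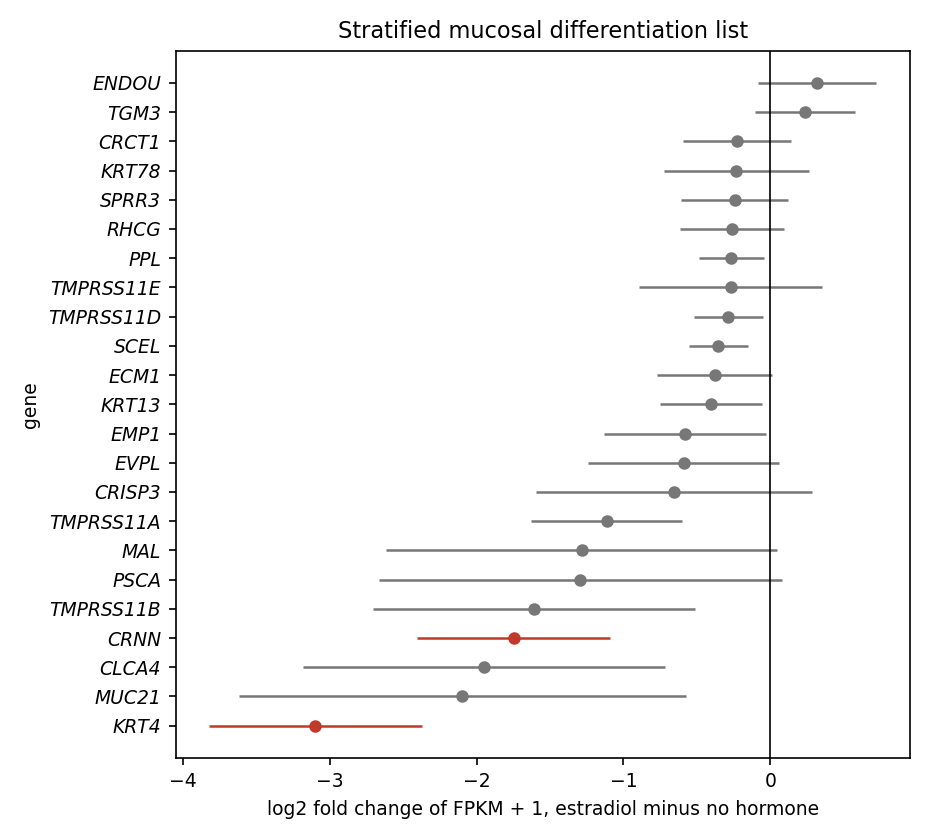
Change with estradiol against no hormone, on the log2(FPKM + 1) scale, of the 23 tested members of the stratified mucosal differentiation list; points are fitted differences, bars their 95% intervals, and red marks the genes past the threshold over all genes. KRT4 (-3.10) and CRNN (-1.75) passed, and 2 members had a positive change.

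Genes with a known response to estrogen did not rise as a list. Of 16 members tested, GREB1 rose and the other 15 did not pass, among them CA12 (12.7 ± 2.51 and 15.8 ± 2.70 FPKM without and with estradiol) and XBP1 (23.4 ± 5.11 and 23.7 ± 3.90 FPKM), with a camera adjusted p = 0.525. The androgen-responsive list (17 members, adjusted p = 0.769) held 1 lower member adjusted over the list alone, the prostaglandin dehydrogenase gene HPGD (-0.44). The steroid-metabolizing enzymes (18 members, adjusted p = 0.197) likewise held 1, the estrogen sulfotransferase gene SULT1E1, at 2.56 ± 0.768 FPKM without hormone and 1.07 ± 0.109 FPKM with estradiol (-0.76). The 4 steroid receptor genes tested had a median change of -0.04, too few members for camera. ESR1, the estrogen receptor alpha gene, was at 0.974 ± 0.689 FPKM without hormone and 0.870 ± 0.444 FPKM with estradiol (log2 change -0.04, limma adjusted p = 0.978), and its sign changed with a pseudocount of 0.1 (0.06) and with quantile scaling (0.0086).

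Water and ion transport held 4 members past the threshold adjusted over the list alone, and none over all genes. The aquaporin genes AQP5 (0.71) and AQP9 (0.35) rose, and the proton pump gene ATP12A (-0.53) and the sodium channel gene SCNN1A (-0.44) fell (20 members, camera adjusted p = 0.358). On the same count the junction protein gene CGN fell (-0.79, 32 members, adjusted p = 0.954) and the interleukin-36 receptor antagonist gene IL36RN rose (0.52, 24 inflammatory members, adjusted p = 0.769). In the oxidative stress list NQO1 rose (0.48) and PGD fell (-0.35), with an adjusted p = 0.769 over 19 members. The collagen genes COL5A1 (0.37) and COL6A1 (0.20) rose among 8 fibroblast and smooth muscle markers (adjusted p = 0.197). None of these members passed over all genes. The median of the cell junction, oxidative stress and matrix lists was positive where camera's direction was down, as was the mean of the cornification list. The median and mean of the mitochondrial list were negative where camera's direction was up.

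In the remaining lists no member passed with estradiol. The camera adjusted p was 0.0581 for interferon-stimulated genes, of which 13 of 14 were negative, 0.0738 for proliferation and for antimicrobial defence, and 0.110 for hypoxia and glycolysis. It was 0.165 for desquamation, 0.197 for basal markers, 0.381 for barrier lipids and 0.528 for cholesterol and fatty acid synthesis. It was 0.769 for matrix remodelling and for immediate-early and heat shock genes, 0.918 for cornification and for glycogen metabolism, and 0.954 for mitochondrially encoded genes. The proliferation marker MKI67 was at 2.51 ± 0.195 FPKM without hormone and 1.84 ± 0.789 FPKM with estradiol (log2 change -0.34), and FKBP5, a glucocorticoid-responsive gene, at 0.476 ± 0.0828 and 0.547 ± 0.0846 FPKM. Markers of immune cells (2 members, median -0.25), endothelium (4, -0.09) and melanocytes (2, 0.24) were too few for camera. The mucosal list was the 1 list of 23 past the threshold and passed without each library in turn, but not with an estimated correlation (adjusted p = 0.178), which left 0 lists. Splits that mixed the estradiol libraries with those without hormone called up to 13 lists. Passing camera therefore does not by itself tie a list to estradiol. The number of lists was 5 and 2 without no hormone replicates 2 and 3, 6 without estradiol replicate 2, 3 without each of testosterone replicates 1 and 3, and 2 without DHT replicate 3.

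Testosterone at 150 nM was compared with no hormone next. No gene passed the threshold of limma, with 630 of 11239 genes at an unadjusted p under 0.05 against 562 by chance and a smallest adjusted p of 0.307. That smallest value belonged to IRAK1, a kinase of interleukin-1 receptor signalling, at 26.9 ± 3.27 FPKM without hormone and 14.3 ± 1.11 FPKM with testosterone (log2 change -0.86). The early response gene FOS was at 2.83 ± 0.817 and 1.40 ± 0.179 FPKM (log2 change -0.65, limma adjusted p = 0.681 over all genes), and it alone fell adjusted over its list. PAK6 (-0.51), IFNLR1 (-0.47), GATSL2 (-0.46), MAP1LC3B (0.49) and TAF9 (0.58) were others of lowest p, none past the threshold (limma adjusted p = 0.681 each). BIVM-ERCC5 (-2.33) and AC023055.1 (2.55), also among them, are models that overlap other genes and are uncertain. The androgen-responsive list had 11 of 17 members positive (camera adjusted p = 0.878), and FKBP5 was at 0.458 ± 0.0242 FPKM. The count of genes was 1 without no hormone replicate 1, 2 without no hormone replicate 2, 2 without testosterone replicate 2, 1 without DHT replicate 3 and 4 with only the libraries compared.

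With testosterone 3 lists passed camera, each at an adjusted p = 0.0463 and each at an adjusted p = 0.963 with an estimated correlation, and no member of the 3 passed. Basal markers were lower (15 of 18 members negative), as with the hemidesmosome collagen gene COL17A1 at 261 ± 31.1 FPKM without hormone and 215 ± 58.9 FPKM with testosterone. Cornification was lower (25 of 37 members negative), as with the filaggrin gene FLG at 797 ± 88.3 and 710 ± 207 FPKM. Inflammatory cytokines were higher (19 of 24 members positive), as with IL1A at 53.5 ± 14.2 and 82.2 ± 13.8 FPKM. Over 18 alternatives the adjusted p ranged from 4.99e-04 to 0.963 for basal markers, 6.11e-07 to 0.987 for cornification and 0.00151 to 0.963 for cytokines, and neither median-of-ratios nor quantile scaling left a list past the threshold. The basal call was lost without no hormone replicates 1 (adjusted p = 0.237) and 3 (0.443), estradiol replicate 2 (0.0508), testosterone replicate 3 (0.246) and DHT replicates 2 (0.0597) and 3 (0.0621). The cornification call was lost without no hormone replicate 3 (0.987), estradiol replicate 2 (0.0508), testosterone replicate 1 (0.866, direction up) and DHT replicate 3 (0.0621), and the cytokine call without no hormone replicate 2 (0.685) and testosterone replicate 3 (0.273). Markers of glandular or columnar epithelium were positive in 8 of 8 members without passing, with a median of 0.36 and an adjusted p = 0.160. The number of lists was 1 without estradiol replicate 2, 5 without testosterone replicate 2 and 1 without DHT replicate 3.

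DHT at 15 nM against no hormone also gave no gene past the threshold of limma, with 1030 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.302. The ubiquitin ligase gene TRIM32 had that value, at 1.52 ± 0.0571 FPKM without hormone and 2.70 ± 0.219 FPKM with DHT (log2 change 0.55). IRAK1 was at 15.9 ± 3.02 FPKM with DHT (log2 change -0.73, limma adjusted p = 0.362). CPSF4 (-0.58), SUOX (0.64), RSL24D1 (0.57), MTG1 (0.51), MPDU1 (0.64), OXLD1 (0.74) and METAP2 (0.49) were the others of lowest p, none past the threshold (limma adjusted p = 0.362 to 0.452). HNRNPUL2-BSCL2 (-1.20), a read-through model over other genes, is uncertain. Adjusted over their lists alone, AQP5 fell from 12.3 ± 2.05 to 6.26 ± 1.02 FPKM (-0.87), the heme oxygenase gene HMOX1 from 178 ± 16.3 to 130 ± 8.15 FPKM (-0.45) and the sphingomyelinase gene SMPD3 from 52.1 ± 4.87 to 38.4 ± 1.33 FPKM (-0.43). In DHT 1633 genes (14.5%) did not overlap the libraries without hormone, against a chance share of 10%, and 1156 (10.3%) did so with testosterone. The median log2 change over all genes was 0.0479 with DHT, against 0.00690 with testosterone and 0.00285 with estradiol. Such a shift can raise the share without overlap and the number of positive list members. After median-of-ratios scaling the DHT median was -0.00594, and 904 genes had an unadjusted p under 0.05 by limma. The count of genes was 1 without no hormone replicate 1, 1 without no hormone replicate 3, 1 without testosterone replicate 2, 1 without DHT replicate 1 and 4 without DHT replicate 3.

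With DHT 8 lists passed camera, and 0 with an estimated correlation. Cornification was lower (30 of 37 members negative, adjusted p = 3.31e-09, adjusted p = 0.307 with an estimated correlation, range over 18 alternatives 5.74e-12 to 0.307). Its members did not all move together. The loricrin gene LOR was at 1642 ± 303 FPKM without hormone and 1392 ± 150 FPKM with DHT, and KRT1 at 544 ± 120 and 633 ± 111 FPKM. Mucosal differentiation was lower (18 of 23 negative, adjusted p = 2.23e-05, adjusted p = 0.307 with an estimated correlation, range 1.22e-06 to 0.307), with KRT4 at 47.1 ± 13.9 FPKM. Glandular or columnar markers were negative in 7 of 8 members beside it without passing, with a median of -0.15 and an adjusted p = 0.126. Proliferation was higher (29 of 32 positive, adjusted p = 1.27e-04, adjusted p = 0.441 with an estimated correlation, range 1.91e-05 to 0.441). Its member PCNA was at 25.5 ± 2.11 FPKM without hormone and 34.4 ± 2.38 FPKM with DHT, and MKI67 at 2.51 ± 0.195 and 2.24 ± 1.17 FPKM. Water and ion transport was lower (adjusted p = 3.98e-04, adjusted p = 0.307 with an estimated correlation, range 1.17e-04 to 0.307). These 4 calls held without each of the 12 libraries in turn. None of the members of these lists but AQP5 passed adjusted over the list alone. Splits that mixed the DHT libraries with those without hormone called up to 14 lists. Passing camera therefore does not by itself tie a list to DHT.

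The other 4 lists lower with DHT lost their calls without single libraries. Desquamation had an adjusted p = 0.00377 (adjusted p = 0.452 with an estimated correlation, range 0.00108 to 0.452), with the kallikrein gene KLK5 at 587 ± 58.4 FPKM without hormone and 477 ± 42.7 FPKM with DHT, and was at 0.0622 without no hormone replicate 3. Antimicrobial defence had an adjusted p = 0.0267 (adjusted p = 0.766 with an estimated correlation, range 0.00276 to 0.766) and was at 0.0558 and 0.286 without no hormone replicates 1 and 3 and 0.0588 without DHT replicate 1. Barrier lipids, with SMPD3, had an adjusted p = 0.0352 (adjusted p = 0.695 with an estimated correlation, range 5.10e-04 to 0.695). They were at 0.680 without no hormone replicate 3 and at 0.0665 and 0.271 without DHT replicates 1 and 3. Cholesterol and fatty acid synthesis, with 17 of 29 members negative, had an adjusted p = 0.0352 (adjusted p = 0.695 with an estimated correlation, range 0.00366 to 0.750). It was at 0.0558 and 0.214 without no hormone replicates 1 and 3 and at 0.750 without DHT replicate 3. The number of lists was 14 without no hormone replicate 2 and 5 without no hormone replicate 3. The androgen-responsive list had 9 of 17 members positive with DHT (adjusted p = 0.667).

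Testosterone and DHT differ by reduction of the A ring, and their doses differed, 150 nM against 15 nM. No gene differed between them past the threshold of limma, with 510 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.930. CPSF4, encoding a subunit of the cleavage and polyadenylation specificity factor, was at 2.79 ± 0.264 FPKM with testosterone and 1.65 ± 0.182 FPKM with DHT, a difference of 0.52 on the log2 scale with a 95% half-width of 0.22. The peroxiredoxin gene PRDX1 was at 263 ± 27.1 and 136 ± 2.91 FPKM (0.94, half-width 0.44). TFG (-0.73, half-width 0.32), YWHAE (-0.62, 0.28) and the spindle gene TPX2 (-0.53, 0.24) were lower with testosterone, each at an adjusted p = 0.930 and so not past the threshold. The median 95% half-width over all genes was 0.282. It was under 1 in 98.9% of genes. Any difference within a gene's half-width of its fitted difference is not excluded, and the half-widths are not adjusted for the number of genes. The count of genes was 2 without no hormone replicate 2, 1 without no hormone replicate 3, 1 without testosterone replicate 2, 1 without testosterone replicate 3, 1 without DHT replicate 1 and 2 without DHT replicate 3.

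By lists, 11 differed between the androgens by camera, and 0 with an estimated correlation. The median difference over all genes was -0.0470, which can by itself raise the number of members lower with testosterone. Proliferation was lower with testosterone than with DHT in all 32 members, of which 2 passed adjusted over the list alone (adjusted p = 5.41e-11, adjusted p = 0.187 with an estimated correlation, range 3.80e-14 to 0.187). Mucosal differentiation was higher in 19 of 23 members (adjusted p = 4.03e-06, adjusted p = 0.187 with an estimated correlation, range 8.37e-07 to 0.187). Inflammatory cytokines were higher in 18 of 24 members (adjusted p = 4.03e-06, adjusted p = 0.187 with an estimated correlation, range 7.41e-07 to 0.187). Markers of glandular or columnar epithelium were higher in 8 of 8 members, with a median of 0.53 (adjusted p = 5.03e-05, adjusted p = 0.245 with an estimated correlation, range 1.43e-05 to 0.245). Among them KRT7 was at 17.0 ± 8.90 FPKM with testosterone and 9.67 ± 5.45 FPKM with DHT, with testosterone replicate 3 highest at 26.6 FPKM. Water and ion transport was higher in 12 of 20 members (adjusted p = 0.00157, adjusted p = 0.187 with an estimated correlation, range 6.00e-04 to 0.187).

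A further 6 lists were higher with testosterone than with DHT, and each lost its call without 1 or more libraries. Without testosterone replicate 3, cornification (adjusted p = 1.93e-05, adjusted p = 0.352 with an estimated correlation, range 6.95e-10 to 0.522) was at 0.145 and antimicrobial defence (2.92e-04, adjusted p = 0.352 with an estimated correlation, range 1.10e-07 to 0.862) at 0.862. Desquamation (0.00492, adjusted p = 0.352 with an estimated correlation, range 6.37e-06 to 0.786) was at 0.536 without that library and 0.0527 without DHT replicate 1. Immediate-early and heat shock genes (0.00917, adjusted p = 0.352 with an estimated correlation, range 0.00210 to 0.352) were at 0.151 without testosterone replicate 3 and 0.350 without DHT replicate 3. Mitochondrially encoded genes (0.0135, adjusted p = 0.584 with an estimated correlation, range 2.49e-05 to 0.584) were at 0.170 and 0.0706 without testosterone replicates 2 and 3 and 0.498, with the direction down, without DHT replicate 1. The oxidative stress list (0.0157, adjusted p = 0.526 with an estimated correlation, range 0.00101 to 0.615) was at 0.158 without testosterone replicate 2 and 0.615 without DHT replicate 3. The number of lists was 7 without testosterone replicate 3.

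The androgens were compared with estradiol directly. KRT4 was higher with testosterone, at 49.4 ± 20.1 FPKM, than with estradiol (log2 difference 2.35, limma adjusted p = 0.0169), and so were CRNN (1.66), SERPINB12 (1.45) and UPK1B (1.27). FAM3D, encoding a secreted protein, was at 18.8 ± 6.18 FPKM with testosterone and 4.84 ± 1.99 FPKM with estradiol (1.77). NTS was lower with testosterone, at 79.0 ± 18.5 FPKM (-2.45, limma adjusted p = 0.00162), as were ANPEP (-1.80), SPINK9 (-1.12), GREB1 (-1.05) and IL1R2 (-1.01). Of 11239 genes, 40 passed, 18 higher and 22 lower, with 1396 at an unadjusted p under 0.05, and 1977 (17.6%) had no overlap against a chance share of 10%. NTS, ANPEP, SPINK9 and UPK1B passed without each library in turn, while without estradiol replicate 1 KRT4, FAM3D, CRNN, SERPINB12, GREB1 and IL1R2 did not. With only the libraries compared FAM3D and GREB1 did not pass, and the difference of GREB1 was -3.40 with a pseudocount of 0.1. The count was 6, 16 and 15 without estradiol replicates 1, 2 and 3, 15, 10 and 12 without testosterone replicates 1, 2 and 3, and 19 and 15 without DHT replicates 1 and 2. The named genes that passed were 8 of 10 without no hormone replicate 2, 6 and 5 without estradiol replicates 2 and 3, 6 without each testosterone library, and 7 without each of DHT replicates 1 and 2. Over the 12 fits without single libraries, FAM3D and CRNN each kept their call in 3 and SERPINB12 in 4. KRT4 kept it in 8, GREB1 in 9 and IL1R2 in 10.

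Mucosal differentiation was higher with testosterone than with estradiol in 22 of 23 members (camera adjusted p = 6.31e-09, adjusted p = 0.270 with an estimated correlation, range 5.98e-10 to 0.270), and 8 members passed adjusted over the list alone. Glandular or columnar markers were higher beside it in 8 of 8 members (adjusted p = 0.00165, adjusted p = 0.454 with an estimated correlation, range 5.91e-05 to 0.454). KRT19 was at 79.5 ± 30.6 FPKM with testosterone and 34.1 ± 26.3 FPKM with estradiol. Proliferation was lower in 28 of 32 members (adjusted p = 7.16e-04, adjusted p = 0.454 with an estimated correlation, range 3.62e-06 to 0.454). Basal markers were lower in 16 of 18 members (adjusted p = 0.00128, adjusted p = 0.339 with an estimated correlation, range 5.25e-04 to 0.339). Interferon-stimulated genes were higher (adjusted p = 0.0150, adjusted p = 0.684 with an estimated correlation, range 0.00185 to 0.684), and were at 0.0935 without estradiol replicate 1 and 0.104 without testosterone replicate 3. Antimicrobial defence was higher (0.0151, adjusted p = 0.784 with an estimated correlation, range 5.47e-05 to 0.880), and was at 0.121 without estradiol replicate 3 and 0.880 without testosterone replicate 3. Inflammatory cytokines were higher (0.0167, adjusted p = 0.597 with an estimated correlation, range 0.00102 to 0.597), and were at 0.318 and 0.104 without the same libraries.

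With DHT, KRT4 was at 47.1 ± 13.9 FPKM and so higher than with estradiol (log2 difference 2.33, limma adjusted p = 0.0143). The alcohol dehydrogenase gene ADH7 was at 9.91 ± 0.971 FPKM with DHT and 3.08 ± 0.793 FPKM with estradiol (1.43), and LCE5A (1.39), SERPINB12 (1.32) and UPK1B (1.30) were also higher. NTS was lower with DHT, at 60.1 ± 13.1 FPKM (-2.83, limma adjusted p = 6.88e-04), as were ANPEP (-1.73), SPINK9 (-1.38) and GREB1 (-1.05). AQP5 was at 6.26 ± 1.02 FPKM with DHT and 21.2 ± 6.48 FPKM with estradiol (-1.58). In all 54 genes passed, 27 higher and 27 lower, with 1098 at an unadjusted p under 0.05, and 1831 (16.3%) had no overlap against a chance share of 10%. The median difference over all genes was 0.0509, and such a shift can also raise the share without overlap. NTS, ANPEP, SPINK9 and UPK1B passed without each library in turn, while without estradiol replicate 1 KRT4, ADH7, LCE5A, SERPINB12, AQP5 and GREB1 did not. With only the libraries compared SERPINB12, AQP5 and GREB1 did not pass, median-of-ratios and quantile scaling each ended the call of SERPINB12, and the difference of GREB1 was -3.44 with a pseudocount of 0.1. The count was 6, 10 and 16 without estradiol replicates 1, 2 and 3, 21 and 20 without testosterone replicates 1 and 2, 13, 11 and 15 without DHT replicates 1, 2 and 3, and 23 with only the libraries compared. The named genes that passed were 5 and 6 of 10 without estradiol replicates 2 and 3, and 6, 6 and 5 without DHT replicates 1, 2 and 3. They were 8 without each of testosterone replicates 1 and 2 and 9 without each of no hormone replicates 1 and 3. Over the 12 fits without single libraries, ADH7 and SERPINB12 each kept their call in 3 and LCE5A in 7. KRT4 and AQP5 each kept it in 8 and GREB1 in 9.

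Between DHT and estradiol 2 lists passed camera. Cornification was lower with DHT in 30 of 37 members, of which 4 passed adjusted over the list alone (adjusted p = 1.30e-07, adjusted p = 0.869 with an estimated correlation, range 2.02e-09 to 0.869). Mucosal differentiation was higher in 17 of 23 members, of which 5 passed adjusted over the list alone (adjusted p = 0.0180, adjusted p = 0.869 with an estimated correlation, range 9.65e-05 to 0.869). Glandular or columnar markers were positive in 6 of 8 members beside it without passing, with a median of 0.23 and an adjusted p = 0.572. The mucosal call was lost without estradiol replicate 3 (0.139) and DHT replicate 3 (0.189). The number of lists was 4 without estradiol replicate 2, 4 without DHT replicate 1 and 1 without DHT replicate 3.

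Of the 31 estradiol genes, 31 with testosterone and 30 with DHT lay closer to their level without hormone than to that with estradiol. The exception was FAM213A, at 0.42 with DHT (half-width 0.24) against 0.71 with estradiol, and OSBP2 was at -0.36 with DHT (half-width 0.21) against -0.74. The median absolute log2 change of the 31 was 0.97 with estradiol, 0.10 with testosterone and 0.10 with DHT, and 0 of the 31 passed with either androgen when adjusted over these genes alone. Of the 31, 24 had the same sign with testosterone as with estradiol and 25 with DHT. Over all genes, unchanged groups simulated against the shared controls had the same sign in 66.7%. That share was not simulated for genes chosen for their estradiol change, so it cannot show whether 24 or 25 exceed chance. KRT4 was at -0.74 with testosterone and -0.77 with DHT, each with a 95% half-width of 0.72, CRNN at -0.09 and -0.64 (0.66) and STC1 at 0.49 and 0.58 (0.53). In all 31, which were chosen for their change against no hormone, the estradiol libraries also lay outside the range of the 9 other libraries. All 31 already had no overlap with the 3 of these 9 without hormone. Over all genes 410 (3.65%) lay outside the 9, against 0.909% for exchangeable libraries. Between testosterone and DHT the median absolute difference of the 31 was 0.07, with a median half-width of 0.27, and 0 passed over these genes alone. Of the 31, 25 passed against testosterone, 25 against DHT and 22 in all comparisons with estradiol. Independent lists of those sizes would share 0.0294 higher and 0.0256 lower genes for testosterone, and 0.0360 and 0.0384 for DHT, and unchanged groups simulated against shared estradiol libraries shared 0 and 0.04 genes. Unchanged groups give almost no calls to share, and independent lists have no libraries in common. Neither figure therefore measures what the shared estradiol libraries add to the overlap. The 3 estradiol libraries could not be split into parts of at least 2, so part of the excess may come from these shared libraries.

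**Figure D3:**
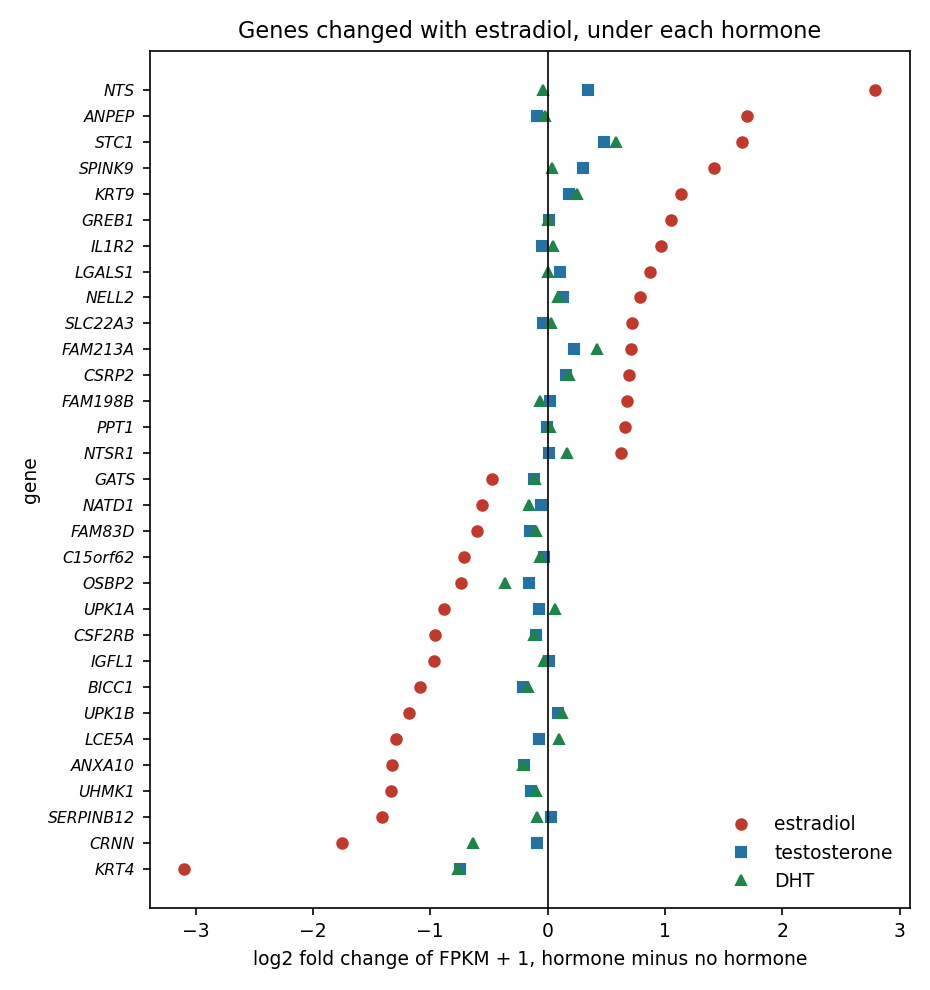
Change on the log2(FPKM + 1) scale (horizontal axis) of the 31 genes past the threshold with estradiol (vertical axis) under estradiol, testosterone and DHT, each against no hormone; each point is the fitted difference of 3 against 3 libraries. The median absolute change is 0.97 with estradiol and 0.10 with each androgen.

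Across all 11239 genes, which are not independent replicates, the log2 changes of estradiol and DHT correlated at r = 0.517 (Spearman's rho 0.486), those of testosterone and DHT at r = 0.4997 (0.540) and those of estradiol and testosterone at r = 0.260 (0.306). Unchanged groups simulated against the same controls gave r = 0.501. The covariance minus the simulated covariance of 0.0153 was 0.0101 for estradiol and DHT, 0.00436 for testosterone and DHT and -0.00364 for estradiol and testosterone. The share of genes with the same sign was 67.0%, 69.8% and 61.8% in that order, against 66.7% simulated. Shared controls alone thus gave an r near that of testosterone and DHT and of estradiol and DHT, and above that of estradiol and testosterone. The correlations therefore do not show a common response. The 3 libraries without hormone could not be split into parts of at least 2, so what the shared controls add could not be removed. Without single libraries, r ranged from 0.409 to 0.651, 0.386 to 0.609 and 0.161 to 0.466. The lowest r of estradiol and testosterone, 0.161, came without testosterone replicate 2 and the highest, 0.466, without no hormone replicate 3. With both androgens averaged against no hormone, 0 genes passed limma, with 939 at an unadjusted p under 0.05 and a smallest adjusted p of 0.167. That count was 1 without each of no hormone replicate 1, estradiol replicate 2, testosterone replicate 2 and DHT replicate 1, and 3 without DHT replicate 3. Camera gave lower cornification (adjusted p = 3.61e-06, adjusted p = 0.911 with an estimated correlation), mucosal differentiation (0.0204, adjusted p = 0.914 with an estimated correlation) and water and ion transport (0.0204, adjusted p = 0.911 with an estimated correlation).

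The transcript table gave 18 transcripts past the threshold of limma with estradiol, 8 with testosterone and 7 with DHT, of 26382 tested, with 1596, 1460 and 1630 at an unadjusted p under 0.05. With estradiol, 8 of the 18 belonged to genes past the threshold, NTS, SPINK9, KRT9, ANPEP, KRT4, GREB1, OSBP2 and ANXA10. With the androgens none of the 15 did. A transcript of the sphingomyelinase gene SMPD3 (ENST00000568373.5_1), on chromosome 16 at 68395030 to 68406161, fell from 8.10 ± 0.756 FPKM without hormone to 0.518 ± 0.101 FPKM with estradiol and 0.575 ± 0.191 FPKM with testosterone. With DHT its libraries were at 7.65, 6.77 and 8.27 FPKM. A transcript of ARHGEF2, a guanine nucleotide exchange factor gene, fell from 4.35 ± 1.14 FPKM to 0.322 ± 0.0957 FPKM with estradiol and 0.573 ± 0.210 FPKM with testosterone. A transcript of WBP2 was at 33.4, 38.5 and 26.9 FPKM in the libraries without hormone and listed at 0 in all 3 testosterone libraries (limma adjusted p = 1.42e-06). The other transcripts of WBP2 summed to 11.1 FPKM without hormone and 20.3 FPKM with testosterone. A transcript of the calcium pump gene ATP2B4 was listed at 0 in all libraries without hormone and was at 10.7 ± 0.844 FPKM with DHT (limma adjusted p = 0.0339). It was at 2.70 FPKM in testosterone replicate 3 and listed at 0 in the other testosterone libraries, and the gene was at 7.17 ± 0.775 FPKM without hormone and 6.35 ± 0.589 FPKM with DHT.

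The counts of transcripts moved with single libraries. With estradiol the count was 10 without no hormone replicate 2, 6, 3 and 7 without estradiol replicates 1, 2 and 3, 11 without testosterone replicate 2 and 11 without DHT replicate 2. With testosterone it was 4 without estradiol replicate 3, 5 without testosterone replicate 3, and 15 and 3 without DHT replicates 1 and 2. With DHT it was 17 and 11 without no hormone replicates 1 and 2, and 1 without DHT replicate 2. A transcript listed at 0 in every library of 1 of the 2 groups compared occurred among 3 of the 18, 4 of the 8 and 4 of the 7. The summed value of a gene's listed transcripts exceeded the gene's own value in 80.4% of 11059 genes, so the transcript and gene values are not on 1 additive scale.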

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

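The tests of estradiol against the 9 other libraries, with overlapping genes left out and with a within-group axis as a covariate were chosen after the results were seen. This axis is the main direction in which libraries of one group varied, in the groups without estradiol. Of 1779 alternative values of 100 named gene values, 1593 kept their direction and side of the threshold, 167 fell short of it, 9 newly passed and 10 changed sign. Only 44 of the 100 were past the threshold, and the others mostly kept their side by staying short of it. Of the 44, 22 passed in every alternative that kept all libraries. Fits in which a gene fell below the filter are not among the 1779. Depth is unknown for FPKM, so its effect on precision could not be computed, and count-based tests were not run. For values that moved, the cause was not tested. Where fewer libraries entered the fit, lower precision and the influence of the libraries left out were not told apart.

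With only the libraries compared, 18 genes passed with estradiol against no hormone, 4 with testosterone and 23 for DHT against estradiol. Estradiol against the 9 other libraries gave 96 genes, which included 30 of the 31. For the averaged androgens, quantile normalization gave 1 gene and the within-group axis as a covariate gave 1. For transcripts, a pseudocount of 0.1 gave 11 with estradiol and 3 with DHT, and the strict filter gave 10 and 2. With an estimated correlation 0 lists passed in each of the 6 comparisons. With estradiol 2 lists passed with each of a pseudocount of 0.1, median-of-ratios scaling and quantile normalization. Both scalings left 0 lists with testosterone, and quantile normalization left 4 with DHT and 6 between the androgens. The estradiol change of ESR1 became 0.0612 with a pseudocount of 0.1 and 0.0086 with quantile normalization.

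The replicate numbers did not pair the libraries: 3 of 18 same-numbered pairs correlated above 0.1 in their deviations (range -0.353 to 0.303), and 3 of 12 libraries correlated best with their own number. With the replicate block, 25 genes passed with estradiol, all among the 31, 13 for testosterone against estradiol and 11 for DHT against estradiol, and 7, 3 and 1 transcripts with estradiol, testosterone and DHT. Of the named genes, the block ended the calls of NELL2, CRNN and IGFL1 with estradiol. It ended those of KRT4, FAM3D, CRNN and SERPINB12 for testosterone against estradiol, and of KRT4, ADH7 and SERPINB12 for DHT against estradiol. Lists with the block numbered 7 with DHT and 3 for DHT against estradiol, and the other counts of lists did not move.

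Leaving out each library in turn gave 8 to 36 genes with estradiol, 0 to 2 with testosterone, 0 to 4 with DHT, 0 to 2 between the androgens, 6 to 56 for testosterone against estradiol, 6 to 59 for DHT against estradiol and 0 to 3 for the averaged androgens. It gave 3 to 25, 3 to 15 and 1 to 17 transcripts with estradiol, testosterone and DHT. Lists numbered 1 to 6 with estradiol, 1 to 5 with testosterone, 5 to 14 with DHT, 7 to 13 between the androgens, 5 to 9 for testosterone against estradiol and 1 to 4 for DHT against estradiol. The correlation of log2 changes ranged from 0.161 to 0.466 for estradiol and testosterone, 0.409 to 0.651 for estradiol and DHT and 0.386 to 0.609 for testosterone and DHT. Log2 changes that crossed 0 were ESR1 with estradiol (-0.355 to 0.182), FKBP5 with testosterone (-0.0534 to 0.0264), KRT13 with testosterone (-0.223 to 0.0493) and DHT (-0.0585 to 0.207), and MKI67 with DHT (-0.435 to 0.109).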

Other observations

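The tests of variation within groups, scaling, conversion, small changes, transcript models and overlapping models were all chosen after the results were seen, as was the comparison of estradiol with the 9 other libraries. The counts over other splits of the other comparisons were planned. NTSR1, a receptor of neurotensin, rose with estradiol beside NTS and was chosen after its values were seen. It measured 0.815 ± 0.142 FPKM (SD, n = 3) without hormone and 1.79 ± 0.111 FPKM (n = 3) with estradiol, a log2 change of 0.62 (SE 0.09, limma adjusted p = 0.00977). With testosterone and DHT it was at 0.831 and 1.03 FPKM, and lower than with estradiol by the test of each difference (limma adjusted p = 0.0169 and 0.0442). NTSR1 lies on chromosome 20 at 61340189 to 61394123 of GRCh37.

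The 31 genes that changed with estradiol were set against technical explanations. Variation between libraries of one group, which the labels do not call separate cultures and which may be technical, was taken from the groups without estradiol. It predicted a median share of 0.00304 of their change (-0.00225 to 0.0282 without single libraries, -0.106 to 0.179 over the 31 genes). Genes called by limma vary little within groups, which by itself lowers this share, and 413 genes not called, with changes at least as large as the smallest of the 31, had a median of 0.157. The main axis of that variation held 29.5% of it, and with this axis as a covariate 24 of the 31 still passed. The choice of genes that vary little within groups favours such passing in advance, so this count cannot decide. Variation between libraries of one group stays open as a part of the change. A difference in scaling is argued against by the 29 of 31 that still passed after quantile normalization. For the lower mucosal differentiation list, the within-group axes predicted a share of 0.252 of the mean change (0.170 to 0.327 without single libraries), so part of it may be such variation and an effect of estradiol stays open. That effect on the 31 genes is a hypothesis, found and tested on the same data.

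Under testosterone, a substrate of aromatase, the mean of each of the 31 estradiol genes lay closer to that without hormone than to that with estradiol. Conversion to estradiol predicts a change with testosterone beyond that with DHT, which cannot be aromatized, and the median of that difference was -0.0101 of the estradiol change (-0.0459 to 0.0214 without single libraries). This argues against conversion as large as the 10 nM estradiol effect. An estradiol-like change too small for 3 libraries stays possible, since the interval of the testosterone change lay below 0.5 of the estradiol change in 23 of 31 genes and reached it in the others. The sign was that of estradiol in 24 of 31 genes, a count that shared controls also raise.

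Transcripts changed by an androgen belonged to genes that did not pass. In 12 of 15 the summed other transcripts of the gene moved the other way. These transcripts belong to genes taken as unchanged, which by itself pushes the other transcripts the other way, so whether reads moved between transcript models cannot be told from this count. Of 42 genes with an absolute log2 difference over 1 under an androgen, 52.4% overlapped another listed gene, against 6.71% of all genes (Fisher's exact p = 1.63e-15), consistent with reads shared between overlapping models. Overlap was counted only between listed genes on the same strand. None of the 31 estradiol genes overlapped another on this count. At a share of 6.71% few of 31 would do so, so this does not show them free of shared reads. A change of splicing by androgens was not tested apart from these explanations.

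For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. Of the 10, splits with as many genes as the real one numbered 1 with estradiol (real 31, highest other 24), 10 with testosterone (0 and 1), 10 with DHT (0 and 3) and 10 between the androgens (0 and 3). They numbered 1 for testosterone against estradiol (40 and 1) and 1 for DHT against estradiol (54 and 3). For transcripts they numbered 1 with estradiol (18 and 11), 3 with testosterone (8 and 11) and 6 with DHT (7 and 15). For lists they numbered 10 with estradiol (1 and 13), 10 with testosterone (3 and 10), 5 with DHT (8 and 14), 2 between the androgens (11 and 11), 5 for testosterone against estradiol (7 and 11) and 9 for DHT against estradiol (2 and 9). In each comparison a split that mixed the groups thus called at least as many lists as the real one. The counts of lists therefore do not tie the lists to a hormone.

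For the averaged androgens the real count was 0, so all 84 splits reached it (highest other 4), and the count of splits decides nothing, as for the other comparisons with 0 genes. For estradiol against the 9 other libraries, 100 of the 220 possible splits were used, the real one and others drawn at random. Of these 100, 2 gave as many genes as the real 96, a share under 0.05. That share alone does not tie the 96 genes to estradiol, because the other of these 2 splits gave more genes. With no hormone replicate 3 and estradiol replicates 1 and 2 in one group, it gave 270 genes, of which 0 were among the 31. The same 3 libraries gave the 24 genes above, which points to a structure of the samples other than the hormone, and no biological explanation of it was tested.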
